A study of Mus musculus with 2 samples.

How the data were processed

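The deposited data were 2 single-cell RNA libraries made from kidneys of male C57BL/6 mice aged 11 weeks. Wild-type (WT) animals were compared with animals carrying 1 disrupted copy of Axl (het KO). Axl encodes a receptor tyrosine kinase of the TAM family. Per the labels' protocols, kidneys were digested with Liberase at 0.2 mg/ml for 25 min at 37 °C and passed through strainers of 70 and 40 µm, and the cells were suspended in DMEM with 10% serum. The labels name immune cells as the cell type and whole kidney as the tissue, and no sort is described. The design text gives 3 mice per genotype. Each genotype had 1 library, and nothing ties a cell to a mouse, so the number of replicates was 1 per group and the 3 mice could not be separated.

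The values used were raw counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors deposited as filtered matrices. Cell Ranger 3.1.0 is named in the submitters' processing notes. The genome build behind the counts is not given in the sources used here. Of the 32285 gene identifiers in the matrices, 32235 were found in GENCODE release M21 of the mouse genome (GRCm38), and positions printed below come from that annotation. Before any filter, the WT matrix held 10395 barcodes and 88389030 UMIs, and the het KO matrix held 10203 barcodes and 91623542 UMIs. UMIs per barcode ran from 500 to 101396 in the WT library and from 501 to 103252 in the het KO library.

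Barcodes with at least 200 genes and at most 50% mitochondrial UMIs were used, the wide mitochondrial limit being set for kidney tubule cells. This left 10053 WT and 9711 het KO barcodes. Doublets were called in each library separately with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 8%. Calls used the automatic thresholds of 0.234 in the WT and 0.218 in the het KO library. The call removed 667 WT barcodes (6.64%) and 768 het KO barcodes (7.91%). The remaining 9386 WT and 8943 het KO barcodes are called cells below. Some droplets with RNA of several cells remained, as the doublet score of 0.106 (median) in one of the macrophage-like clusters and plasma cell transcripts in single macrophage-like cells show.

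Cells of both libraries were scaled to 10000 UMIs, log-transformed and clustered together on 2000 variable genes, 30 principal components and a shared-neighbour graph of 15 neighbours, with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). No batch correction was applied, because library and genotype are one and the same here. This gave 33 clusters. A cluster took the name of the class with most of its fixed markers among the cluster's 100 leading genes. It stayed unnamed with under 3 such markers, with more markers of another class in its top 10, or with shallow cells and no own marker in its top 10. The markers were fixed in advance, while this scoring was written after the leading genes of a first clustering had been seen, and no other scoring was tried. Names are written as "X-like" because they rest on markers alone. Axl and Gas6 stood among the macrophage markers. In all, 29 clusters were named and 4 were not, and the unnamed clusters held 187 WT cells (1.99%) and 158 het KO cells (1.77%). The largest of them, with 132 WT and 95 het KO cells, had leading genes of both neutrophils and monocytes.

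With 1 library per genotype no test between genotypes was possible, and no p-value or standard error was computed. Counts were summed over the cells of a class, divided by the class total and given as CPM. The het KO to WT ratio has an exact conditional binomial interval, a CPM an exact Poisson interval and a share of cells an exact Clopper-Pearson interval. All are 95% intervals and cover counting error only, not the differences between mice, digestions or library preparations. Where 1 library had no UMI of a gene, the fold is taken against a floor of 3 counts for the class and is not a lower limit. Shares of cells with a UMI were also computed after each cell was thinned to 1000 UMIs, with shallower cells left out.

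The rule for named genes took genes with at least 50 UMIs over both libraries, ranked by the bound of the ratio's interval nearest to no change. It named 10 genes each way in the proximal tubule, endothelial and macrophage classes and 5 each way in any other class with at least 200 cells in each library. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, predicted-model, Xist and Y-linked genes were left out of the ranking. A small number of named or listed genes are not reported here. Axl, Mertk, Tyro3, Gas6 and Pros1 were taken in every class, and so were the 2 highest and 2 lowest members of each gene list. The 36 gene lists covered cell identity, stress, immune and tubule functions. For each list with at least 4 members of at least 20 UMIs in a class, the median log2 ratio was set beside 10000 random lists of the same size matched on mean expression. The percentile among them describes these libraries and is not a test. Lists for endothelial and stromal cells were not read, because no cluster took those names. A few list or marker symbols were absent from the matrices (Trgc1, Trgc2, Faim3, Mx1, Mx2, Clec7a, Nkcc2, Ctgf and Cyr61).

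The counting steps were run on simulated data. Poisson counts were drawn from the summed WT profile of a class, which is the model the intervals assume. The run therefore checks the calculation only. It does not cover real genes whose UMIs lie in few cells. In macrophage-like cells (10269 genes), 61.2% of genes changed 1.5-fold up or down, 91.5% of those changed 2-fold and 100% of those changed 4-fold or 8-fold had intervals excluding no change, against 4.36% of unchanged genes. In T-like cells (12757 genes) the shares were 84.0%, 100%, 100% and 100%, against 4.59%. A list of 20 genes raised 1.5-fold stood at percentile 100 in both classes (12153 and 14723 genes). An unchanged list stood at percentile 78.4 and 79.2.

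The gene lists, markers, filters, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were a mitochondrial limit of 25% or none, at least 500 genes, called doublets kept, resolutions 0.5 and 2, stress, mitochondrial, ribosomal and hemoglobin genes left out of clustering, CPM without mitochondrial genes, median-of-ratios scaling, thinning, subtraction of free RNA (the profile of all cells of a library, at a share set by proximal tubule genes), the mean over cells, and minimums of 100 UMIs per list member and 200 UMIs per named gene. The free RNA shares would give T-like, NK-like and B-like cells of both libraries more C1qa, C1qb and C1qc transcripts than were measured. These shares are therefore in doubt, and so are all values after that subtraction. Added after seeing the data were the removal of cells with a Scrublet score above 0.1, weighting to the WT cluster make-up, and subtraction of the median ratio of the other classes. Sequence similarity between genes was searched with blastn 2.17.0 over the last 500 bases of transcripts, counting matches of at least 80 bases at 95% identity. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.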

Results

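Kidney cells of WT mice and of mice with 1 disrupted copy of Axl were compared by droplet-based single-cell RNA sequencing with 3' end counting, with 1 library per genotype. The labels state no purpose beyond the comparison of the genotypes. The filtered WT library held 9386 cells with a median of 6546 UMIs, and the filtered het KO library held 8943 cells with a median of 6786 UMIs. Immune classes made up 94.1% of WT and 92.5% of het KO cells, with 197 and 221 tubule epithelial cells beside them. T-like, NK-like and B-like cells were the largest classes in both libraries. None of the 33 clusters took an endothelial or stromal name. Since each genotype had 1 library, no difference below has a replicate check. Ranges in brackets are 95% intervals for counting error alone.

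Axl was highest in macrophage-like cells of both libraries, and was lower there in the het KO library. Axl, a receptor for Gas6, takes part in the uptake of dying cells. In macrophage-like cells it measured 274 CPM (253 to 297; 603 UMIs) in the WT library and 151 CPM (143 to 160; 1264 UMIs) in the het KO library, a ratio of 0.552 (0.501 to 0.609). Both macrophage-like clusters showed this, with ratios of 0.537 (0.479 to 0.602) and 0.582 (0.481 to 0.706). Monocyte-like cells had 12.3 CPM in the WT and 5.57 CPM in the het KO library, a ratio of 0.452 (0.331 to 0.609), or -1.15 on the log2 scale, and -0.46 after thinning. That difference was seen in one of their clusters (18.1 against 5.59 CPM), while another showed 7.17 and 7.23 CPM and the third 1.82 and 3.41 CPM (6 UMIs in each library). Dendritic-like cells had a ratio of 0.492 (0.310 to 0.781).

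Summed over each class, Axl in lymphocytes went the other way, at far lower levels. In NK-like cells Axl was 1.67 CPM in the WT and 5.31 CPM in the het KO library (ratio 3.19, 1.81 to 5.82; 19 and 41 UMIs). In T-like cells the values were 2.44 and 4.08 CPM (1.67, 1.19 to 2.37). The clusters within these classes were uneven. The larger NK-like cluster had a ratio of 6.02 (2.93 to 13.6) and the smaller one 0.366 (0.0824 to 1.31; 9 and 4 UMIs). Among T-like clusters, the one with Cd4 and Lef1 had 4 and 18 UMIs (6.29, 2.07 to 25.6), while the Gzmk, Foxp3 and Klra1 clusters had ratios of 0.793, 1.08 and 1.07, with intervals that included no change. The Trdc cluster had 0 UMIs in 48 WT cells, which allows up to 8.52 CPM, and 4.77 CPM in the het KO library, so a difference was not detectable there. In B-like cells Axl was 0.511 and 1.96 CPM, from 5 and 16 UMIs. Subtraction of free RNA, at 19.9% of the all-cell level in WT and 8.97% in het KO T-like cells, left almost no Axl in WT T-like cells (2.44 CPM subtracted), so the log2 ratio of 3.96 it gave has no meaning as a size. In NK-like cells the log2 ratio after subtraction was 2.70. Summed over all cells, Axl was higher in the het KO library (12.3 against 20.5 CPM), where macrophage-like cells were more frequent.

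At least 1 Axl UMI was found in 84.1% (79.1 to 88.3) of WT and 62.0% (58.8 to 65.2) of het KO macrophage-like cells, at median depths of 6654 and 6991 UMIs. After thinning the shares were 31.0% and 14.1%, with 3 and 10 shallow cells left out. In B-like cells, taken as background although low expression there was not excluded, the share was 0.279% and 1.12% at median depths of 5223 and 5484 UMIs, and 0% and 0.142% after thinning (21 and 11 cells left out). Axl helped name the macrophage-like clusters. Among barcodes of at least 1000 UMIs chosen without clustering, by at least 2 UMIs of the C1q genes after thinning to 1000 UMIs, Axl was 225 CPM (208 to 242) in the WT and 126 CPM (119 to 132) in the het KO library, a choice made after the clusters had been seen. Axl (ENSMUSG00000002602) lies on the minus strand of chromosome 7 from 25757273 to 25788705. The deleted part of the gene is not given in the sources used here. If the 3' end lies outside it, transcripts of the disrupted copy are counted too, and the Axl count then checks nothing about the genotype.

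**Figure D1:**
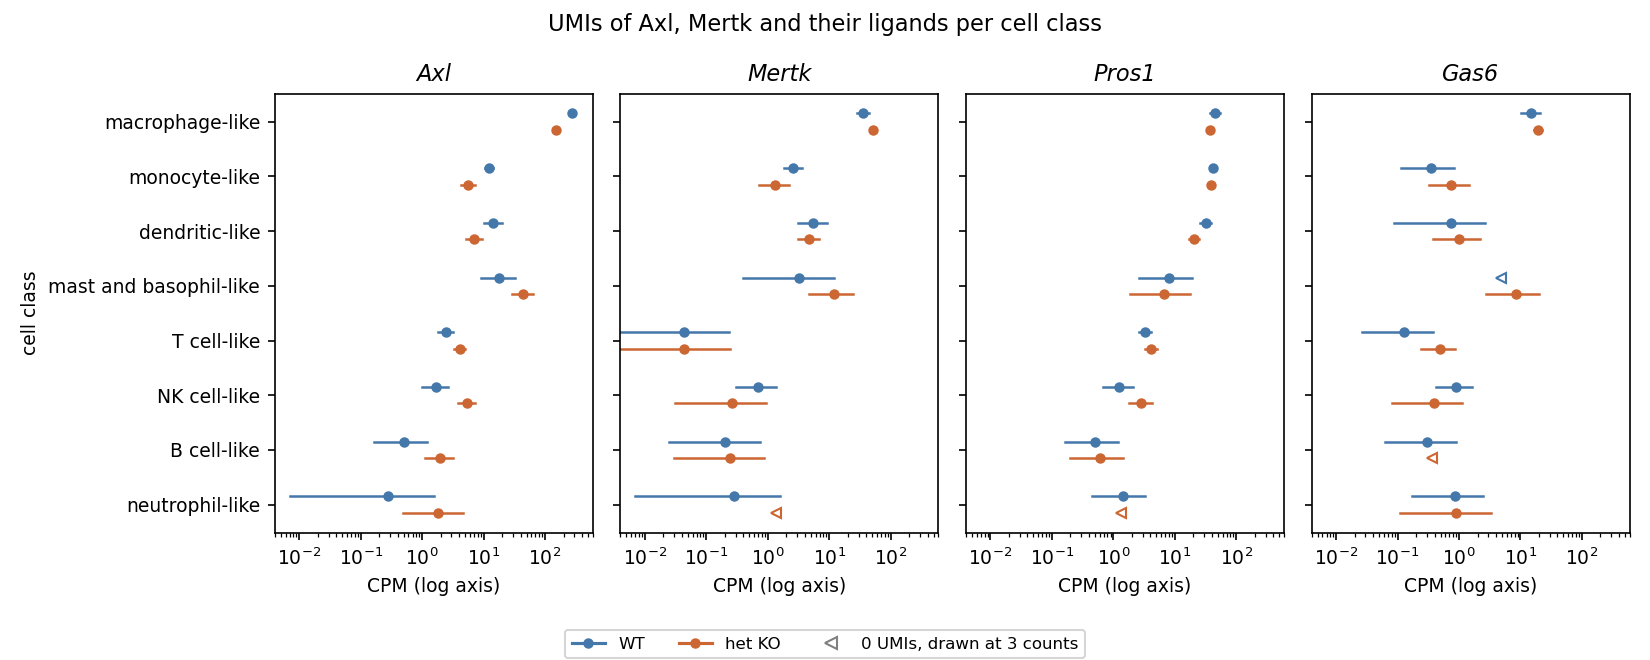
Level of Axl, Mertk, Pros1 and Gas6 in CPM (log axis) in 8 cell classes of the WT (blue) and het KO (orange) library, with lines for the exact Poisson 95% interval and open triangles at 3 counts where no UMI was seen. Axl in macrophage-like cells was 274 CPM in the WT and 151 CPM in the het KO library.

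Mertk, a receptor of the same family (chromosome 2, 128698956 to 128802894), was higher in het KO macrophage-like cells, at 35.5 CPM (28.0 to 44.3) in the WT and 51.5 CPM (46.8 to 56.6) in the het KO library, a ratio of 1.45 (1.14 to 1.87). In the larger macrophage-like cluster the ratio was 1.24 (0.943 to 1.65), and in the smaller one, whose median doublet score was 0.106, it was 2.38 (1.37 to 4.49). Mertk was lower in het KO monocyte-like cells, at 2.59 and 1.30 CPM (ratio 0.501, from 37 and 14 UMIs). This came from one monocyte-like cluster, with 37 and 9 UMIs (0.298, 0.126 to 0.628), while another had 0 and 5 UMIs. Mertk was also lower in distal convoluted tubule-like cells, at 132 and 73.8 CPM (0.558, 0.359 to 0.865). The ligand Gas6 (chromosome 8, 13465374 to 13494490) was highest in tubule cells. It measured 220 and 205 CPM in thick ascending limb-like cells (0.930, 0.783 to 1.10) and 233 and 149 CPM in distal convoluted tubule-like cells (0.640, 0.467 to 0.877; 25 and 29 cells). In macrophage-like cells the Gas6 ratio was 1.30, with an interval that included no change (0.891 to 1.95), and its log2 ratio was 0.38 unthinned and 1.90 after thinning, from 33 WT UMIs before thinning. Pros1, the gene of the ligand protein S (chromosome 16, 62854307 to 62929346), was 45.5 and 37.4 CPM in macrophage-like cells (0.822, 0.654 to 1.04) and 31.8 and 20.4 CPM in dendritic-like cells (0.643, 0.483 to 0.857), and had a ratio of 2.32 (1.14 to 4.91) in NK-like cells, from 14 and 22 UMIs. Tyro3 (chromosome 2, 119797733 to 119818104) was low, with 24 WT and 37 het KO UMIs in T-like cells. The TAM list of 4 read members had a median log2 ratio of 0.05 in macrophage-like cells (percentile 78.1).

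The make-up of the immune cells differed between the libraries. Macrophage-like cells were 2.75% (2.43 to 3.10) of WT and 10.4% (9.77 to 11.1) of het KO cells, a ratio of 3.78 (3.29 to 4.36; 258 and 930 cells). Dendritic-like cells were 1.72% and 4.04% (ratio 2.35, 1.95 to 2.85). NK-like cells were lower in the het KO library, at 19.2% and 13.6%, a ratio of 0.709 (0.658 to 0.763). T-like cells differed little, at 30.7% and 31.4% (1.02, 0.972 to 1.08).

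Both macrophage-like clusters held more het KO cells, with ratios of 3.69 (3.15 to 4.33) and 4.12 (3.07 to 5.62), and 77.8% and 79.7% of their cells came from the het KO library. A cluster made mostly of 1 library may stand for that library and not for a type. Of immune cells alone, macrophage-like cells were 2.92% and 11.2%. Dendritic-like cells were higher both in a cluster led by Siglech, a plasmacytoid gene (ratio 2.67), and in one led by Xcr1 and Clec9a of conventional dendritic cells (2.07). Type 2 innate lymphoid-like cells had a ratio of 1.56 (1.16 to 2.11) and erythroid-like cells one of 2.25 (1.76 to 2.89). Monocyte-like cells (0.785, 0.714 to 0.863), neutrophil-like cells (0.794, 0.712 to 0.886) and B-like cells (0.835, 0.778 to 0.895) were lower. Among tubule classes, proximal tubule-like cells were more frequent in the het KO library (19 against 77 cells; 4.25, 2.55 to 7.44) and thick ascending limb-like cells less frequent (127 against 84 cells; 0.694, 0.521 to 0.922). With cells above a Scrublet score of 0.1 left out, the log2 ratio of the dendritic-like share was 1.55 and that of the thick ascending limb-like share -1.93. The intervals of mast and basophil-like (0.826, 0.554 to 1.23), proliferating (1.30, 0.941 to 1.80) and distal convoluted tubule-like cells (1.22, 0.688 to 2.17) included no change. Erythroid-like cells had a log2 ratio of 0.65 when at least 500 genes were asked for.

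**Figure D2:**
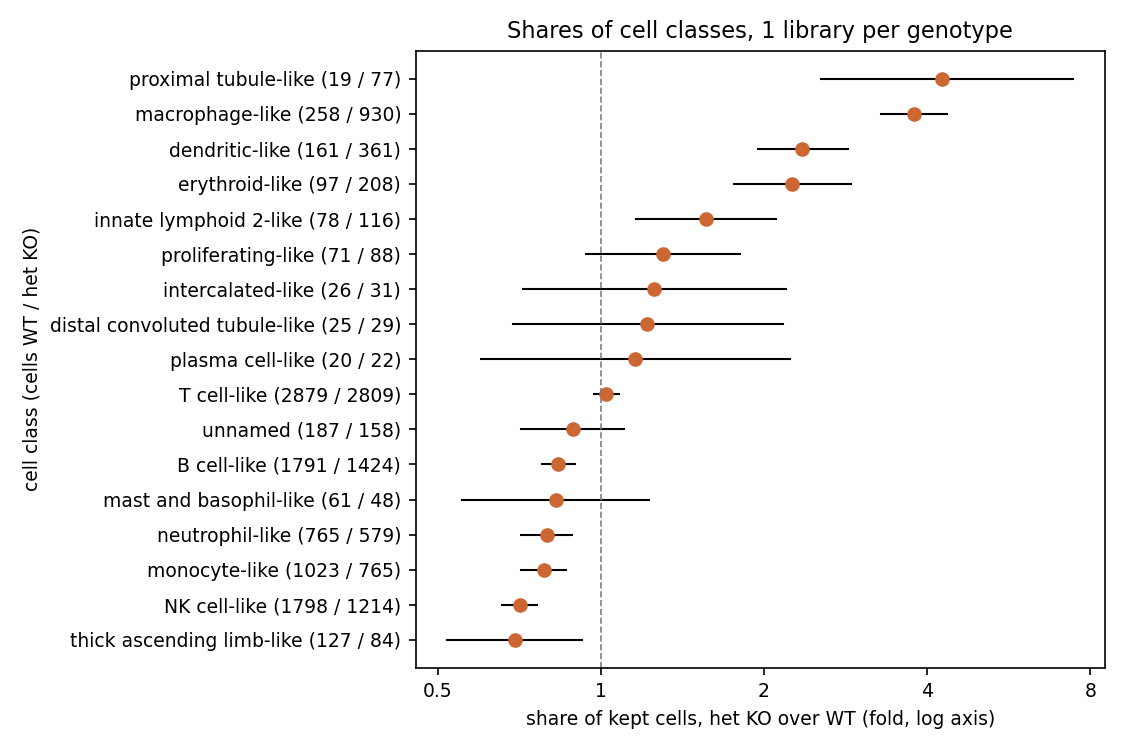
Fold of each class's share of cells, het KO over WT (log axis), with lines for the 95% exact interval and the cells of each library beside the class names. Macrophage-like cells had a ratio of 3.78 and NK-like cells one of 0.709.

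Within T-like cells, both naive-like clusters took a smaller share in the het KO library. The Gzmk cluster took a larger one, as did the cluster with Trdc as its first leading gene, called the Trdc cluster here. A cluster with Cd8b1, Dapl1 and Lef1 held 33.7% (32.0 to 35.5) of WT and 25.0% (23.4 to 26.6) of het KO T-like cells. A cluster with Cd4, Igfbp4 and Lef1 held 27.9% and 20.7%. The cluster with Gzmk, Pdcd1 and Cd8a held 14.8% (13.5 to 16.1) and 23.1% (21.5 to 24.7), a ratio of 1.56 (1.38 to 1.77). The cluster with Trdc, Tcrg-C1 and Gzmb, genes of γδ and cytotoxic T cells, held 1.67% (1.23 to 2.20) and 8.62% (7.60 to 9.71), a ratio of 5.17 (3.78 to 7.20; 48 and 242 cells). The Foxp3 and Ctla4 cluster of regulatory-like cells held 9.52% and 11.3% (1.19, 1.01 to 1.40). The Il23r and Il17a cluster held 3.37% and 3.24% (0.962, 0.714 to 1.29), and the cluster with Klra1, Xcl1 and Cd160 held 9.10% and 8.08% (0.888, 0.740 to 1.06). Trdc was also among the leading genes of both of these clusters. The ratio of 5.17 is thus that of a single cluster and not of γδ T cells as a whole. At resolution 0.5 the Trdc cluster joined the one with Klra1, and the joint log2 ratio of its share was 0.68, against 2.40 for the Trdc cluster alone. Among NK-like cells the larger cluster had a share ratio of 0.659 (0.609 to 0.713) and the smaller one 1.22.

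**Figure D3:**
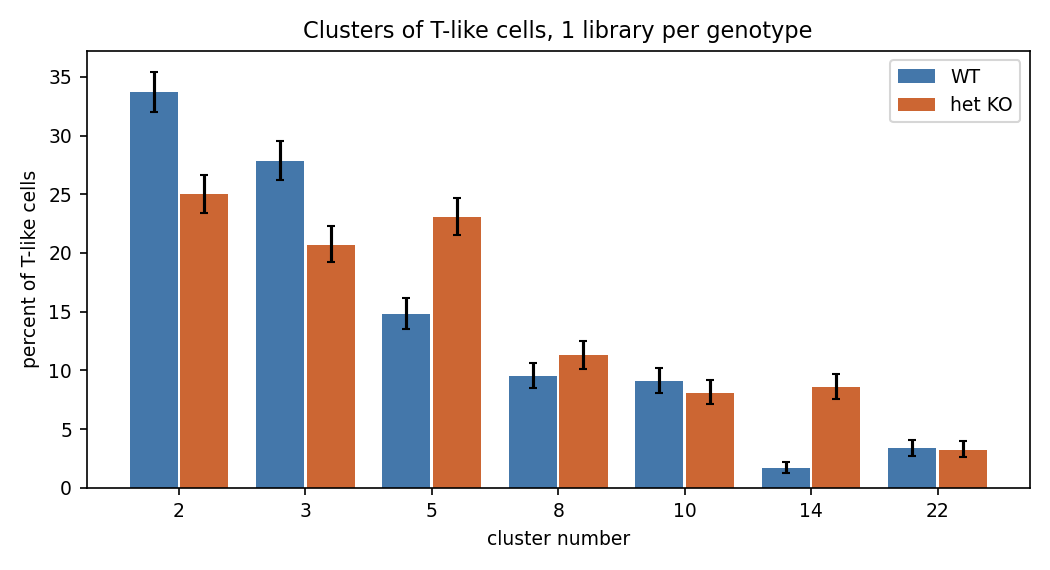
Percent of T-like cells in each of 7 T-like clusters in the WT and het KO library, with error bars for the exact binomial 95% interval. The Trdc cluster (14) held 1.67% of WT and 8.62% of het KO T-like cells.

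Macrophage-like cells of the het KO library had more transcripts of immediate early, inflammatory and endoplasmic reticulum stress genes. Of 30 immediate early and dissociation-linked genes, 27 were higher, each beyond its counting interval, and 3 lower, 1 of them beyond it, with a median log2 ratio of 0.60 (percentile 100; the central 95% of random lists ran from -0.09 to 0.06). Egr1 was 613 and 1272 CPM, Fos 675 and 1174 CPM, Atf3 788 and 1191 CPM and Ier3 42.3 and 108 CPM in the WT and het KO library, while Btg1 was lower at 848 and 646 CPM. Of 37 inflammatory cytokines and NF-kB targets, 28 were higher, 18 of them beyond their interval (median 0.30, percentile 100). The cytokine gene Il1b was 1204 and 1915 CPM, the chemokine gene Cxcl2 427 and 737 CPM and the NF-kB inhibitor gene Nfkbia 299 and 554 CPM. Tnf was close, at 194 and 190 CPM, and Il1a was lower at 34.1 and 17.2 CPM. Of 17 endoplasmic reticulum stress genes, 13 were higher, 9 beyond their interval (0.35, percentile 100), among them the chaperone gene Hspa5 at 472 and 731 CPM. These lists stayed above 0 under every alternative run, at 0.54 to 0.64, 0.22 to 0.34 and 0.11 to 0.39. The endoplasmic reticulum stress list also lay above the random lists in monocyte-, neutrophil-, T-, NK-, B- and dendritic-like cells (medians of 0.16 to 0.43). Its rise is thus not particular to macrophage-like cells.

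Genes of monocyte-derived cells were higher in het KO macrophage-like cells as well, 13 of 17, with 8 beyond their interval (median 0.45, percentile 100). S100a4 was 11.4 and 40.8 CPM and Ifitm6 1.82 and 10.7 CPM. The size of this difference moved with the settings, from 0.09 with members of at least 100 UMIs to 1.27 with free RNA subtracted. Genes of resident macrophages went both ways, 10 higher and 10 lower (0.01, percentile 74.2), and 17 of the 20 also served as markers. The lipid carrier gene Apoe was higher (3960 and 5956 CPM), as was the mannose receptor gene Mrc1 (175 and 257 CPM), and Cd72 was lower (523 and 362 CPM). The p53 list had a median of 0.15 (percentile 99.3), and -0.13 after thinning.

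Lower in het KO macrophage-like cells were genes of interferon response, lysosome, respiration and cell cycle. Of 43 type I interferon genes, 29 were lower, 14 beyond their interval (median -0.14, percentile 1.16), with the antiviral gene Rsad2 at 46.8 and 27.2 CPM and Oas1a higher at 29.1 and 47.0 CPM. Alternatives put this median between -0.23 and -0.0425. Of 35 lysosome genes, 27 were lower, 12 beyond their interval (-0.15, percentile 0.03; -0.24 with free RNA subtracted), with Cd63 at 203 and 152 CPM. Of 65 nuclear genes of oxidative phosphorylation, 50 were lower, 16 of them beyond their interval, and 2 were higher beyond it (-0.13, percentile 0.25), with Sdhb at 82.3 and 58.5 CPM. Cell cycle genes had a median of -0.47 (15 of 20 lower, 8 beyond their interval), with Ube2c at 5.46 and 1.44 CPM, and alternatives put that median between -1.60 and -0.10. Ribosomal protein genes had a median of -0.09 (percentile 0.29). With free RNA subtracted, the respiratory and ribosomal medians were 0.02 and 0.05. Proximal tubule genes were lower in WT than in het KO macrophage-like cells (64.1 and 81.7 CPM). The subtraction still took a larger share from the WT ones (16.9% against 6.56% of the all-cell level), so both medians are in doubt. Efferocytosis genes, for the uptake of dying cells, went both ways (17 higher, 14 lower; 0.03, percentile 88.1), with the receptor gene Lrp1 at 25.5 and 39.4 CPM and the scavenger receptor gene Msr1 at 52.7 and 41.2 CPM. Class II presentation (-0.05, percentile 29.6; 0.11 without the 5 of 12 members that were also markers), class I presentation (-0.03, percentile 53.3), glycolysis (0.01, percentile 73.0) and mitochondrially encoded genes (0.07, percentile 91.0) lay within the random lists.

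Several of the named macrophage genes rested on few cells. Higher in the het KO library were Nbea (2.27 and 30.9 CPM), Il31ra (4.55 and 26.5 CPM), Gstp1 (4.09 and 18.9 CPM), Hist1h2ap (8.64 and 33.9 CPM), Bcl2a1d (37.7 and 113 CPM), S100a4 and Agbl1 (57.3% of het KO UMIs in 5 cells). Jchain, the joining chain of secreted antibodies, was 14.1 and 457 CPM, but 95.3% of the het KO UMIs lay in 5 cells, and its log2 ratio was -0.13 with called doublets kept. The antibody gene Igha went with it, at 35.9 and 831 CPM. Cd209a had 0 WT and 58 het KO UMIs, 5.09-fold higher against the floor of 3 counts, with 91.4% in 5 cells. Lower in the het KO library were Rnaset2a (135 and 29.7 CPM), Rnaset2b (91.4 and 19.3 CPM), AA467197 (52.7% of WT UMIs in 5 cells), Olfr111 (86.0 and 21.8 CPM), Dcstamp, which acts in cell fusion (67.8 and 16.4 CPM, 75.8% of the WT UMIs in 5 cells), and Ckap2l (38.2 and 7.19 CPM, 67.9% in 5 cells). The interferon-induced chemokine gene Cxcl9 (140 and 22.5 CPM) and Frmpd4, Chrm3 and Fam189a2 had 84.0% or more of their WT UMIs in 5 cells. Thinning took the log2 ratio of Hist1h2ap to -0.0031. Gstp1, Hist1h2ap, Bcl2a1d and Rnaset2a differed in nearly every class, and, against the median of the other classes, the log2 ratio in macrophage-like cells was -0.71 for Gstp1, -0.92 for Hist1h2ap and -0.32 for Bcl2a1d. The elastase gene Mmp12, chosen after its values were seen, was lower (610 and 335 CPM).

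**Figure D4:**
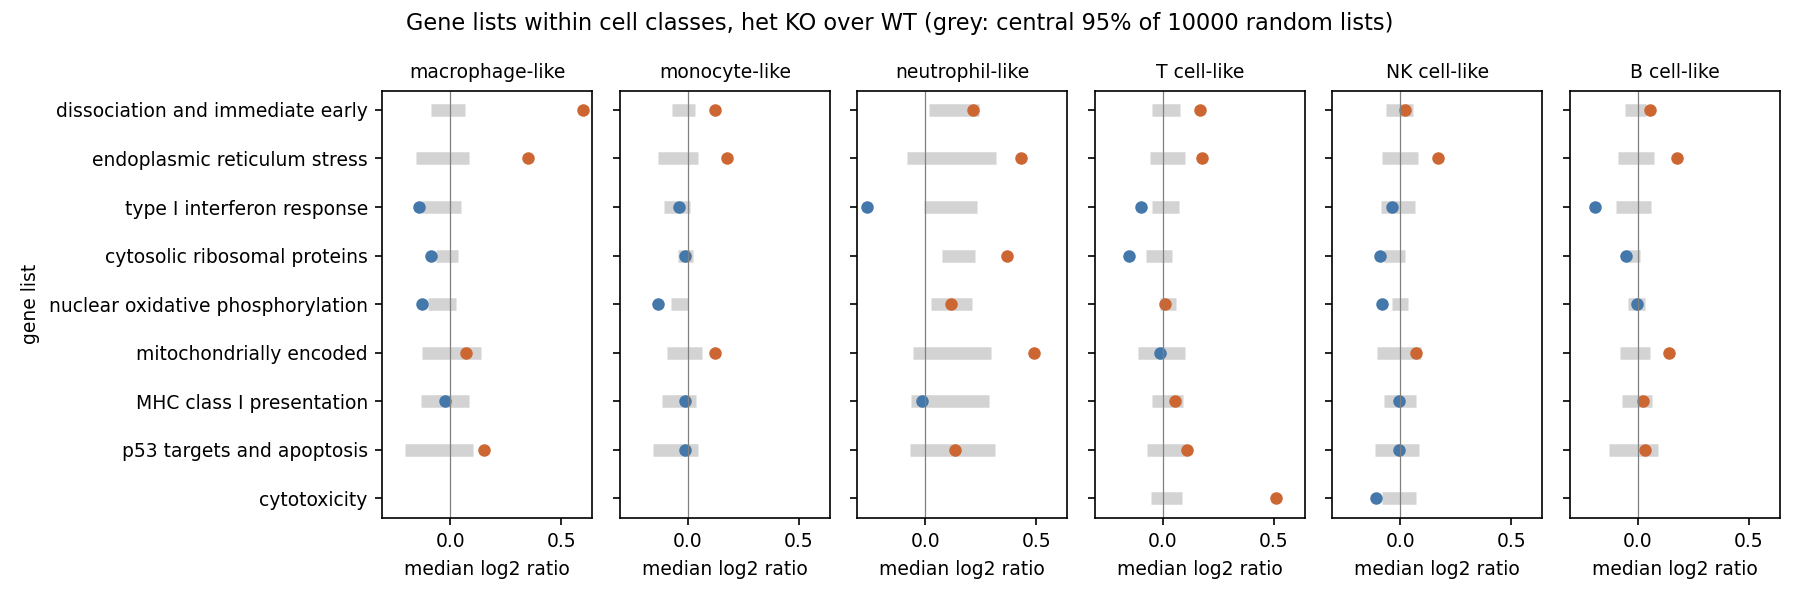
Median log2 ratio, het KO over WT, of 9 gene lists in 6 cell classes (dots), with grey bars for the central 95% of 10000 random lists. Immediate early genes in macrophage-like cells had a median of 0.60 and type I interferon genes in neutrophil-like cells one of -0.26.

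In monocyte-like cells the stress and inflammatory lists had medians above 0 too, smaller than in macrophage-like cells, though not always from the same genes. Genes of respiration and class II antigen presentation were lower in the het KO library. Of 30 immediate early genes 19 were higher, 18 beyond their interval (median 0.12, percentile 100), led by the heat shock genes Hspa1b and Hsph1, the latter at 30.8 and 59.2 CPM. Of 37 inflammatory genes 25 were higher, 17 beyond it (0.13, percentile 100), with Bcl2a1d at 24.0 and 60.6 CPM and Cxcl9, which was lower in macrophage-like cells, at 6.09 and 28.4 CPM. Bcl2a1d was higher in all 6 large immune classes and has near-identical copies, so its value is not particular to monocyte-like cells. The endoplasmic reticulum stress list had a median of 0.17 (16 of 19 higher), and 0.0043 after thinning. Of 65 respiratory genes 61 were lower, 46 beyond their interval (-0.14, percentile 0), with Ndufs8 at 91.0 and 67.5 CPM. Of 12 class II genes 9 were lower, 8 beyond it (-0.15, percentile 0.41), with H2-DMb2 at 47.3 and 30.8 CPM, and the median was -0.41 without cells above a Scrublet score of 0.1. Mitochondrially encoded genes were higher (0.12, percentile 99.7). Their median was 0.03 with at least 500 genes per cell and 0.02 without cells above a Scrublet score of 0.1, within the random lists (up to 0.06).

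The interferon list (-0.04, percentile 67.6) went both ways in monocyte-like cells, with Cxcl10 at 42.6 and 102 CPM and Ifi209 at 143 and 109 CPM. Monocyte-derived identity was close (-0.04, percentile 25.1; 16 of 18 members were also markers), with the matrix gene Fn1 higher (572 and 801 CPM) and Vcan lower (171 and 130 CPM). The p53 (-0.01), class I (-0.01), ribosomal (-0.02) and cell cycle (-0.19) medians stood at percentiles 80.1, 77.9, 31.2 and 14.4. Named genes higher in the het KO library were Gstp1 (8.61 and 65.0 CPM), Hist1h2ap (8.47 and 52.6 CPM), Lyz1 (3.50 and 26.2 CPM, 68.1% in 5 cells), Xlr and Btbd16 (81.1% of het KO UMIs in 5 cells). Lower were the acute-phase gene Saa3 (12.8 and 1.11 CPM, 54.6% of WT UMIs in 5 cells), Lrg1 (18.7 and 3.16 CPM), Tpd52l1 (4.20 and 0.464 CPM), Rnaset2a (105 and 25.2 CPM) and Retnla. The 135 WT UMIs of Retnla lay in 2 cells and the het KO library had none, 34.0-fold lower against the floor of 3 counts. Among genes chosen after their values were seen, Il6 was 4.83 and 12.1 CPM and the lipid receptor gene Trem2 60.8 and 35.9 CPM.

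Neutrophil-like cells of the het KO library had fewer interferon-response transcripts and more ribosomal and mitochondrial ones. Their median over all genes was 0.12, so list values are read against random lists. Of 41 interferon genes 29 were lower, 20 beyond their interval (-0.26, percentile 0), with Ifitm3 at 1444 and 726 CPM, Isg15 at 565 and 375 CPM and Gbp2 at 78.8 and 28.0 CPM, and Bst2 higher at 11.3 and 30.2 CPM. Of 54 ribosomal protein genes 53 were higher, 46 beyond their interval (0.37, percentile 100), and all 13 mitochondrially encoded genes were higher (0.49, percentile 100). These medians were 0.19 and 0.25 with a mitochondrial limit of 25%, and 2.15 for ribosomal genes with free RNA subtracted. Endoplasmic reticulum stress genes were higher (0.43, percentile 99.9), with Hsp90b1 at 26.7 and 48.3 CPM. Median depth was lower in the het KO library (4403 and 3715 UMIs).

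The neutrophil activation list went both ways (0.13, percentile 55.6; 13 of 25 members were also markers), and its median was -0.01 at the 25% limit. Icam1 was 24.8 and 51.9 CPM and the growth factor gene Csf1 76.6 and 139 CPM, while the alarmin gene S100a9 was 86700 and 55236 CPM. The respiratory median (0.12) stood in the middle of the random lists. Immediate early (0.22), p53 (0.13), cell cycle (0.40) and class I (-0.01) medians stood at percentiles 93.8, 53.6, 85.6 and 8.13. Lower by the named-gene rule were Wfdc17 (4735 and 1547 CPM), Ifitm1 (4439 and 1534 CPM), Igfbp6 (125 and 30.7 CPM), Prok2 (37.5 and 4.96 CPM) and Klra4 (54 and 2 UMIs, 81.5% of the WT ones in 5 cells). Higher were Crip1 (51.2 and 200.3 CPM, with 58.3% of the het KO UMIs in 5 cells and a log2 ratio of 0.77 after thinning, against 1.97), Hist2h2aa1 (13.2 and 77.2 CPM), Il31ra (5.35 and 29.3 CPM) and the macrophage genes C1qa and C1qb, the latter at 2.53 and 28.9 CPM. C1qa was higher in lymphocyte classes too, at 3.86 and 12.4 CPM in NK-like and 3.88 and 13.4 CPM in B-like cells.

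T-like cells of the het KO library had more cytotoxic and activation transcripts and fewer naive ones. All 20 cytotoxicity genes were higher, 19 beyond their interval (median 0.51, percentile 100). Granzyme genes led, with Gzmk at 20.9 and 56.5 CPM, Gzmb at 51.1 and 126 CPM and Gzma at 159 and 302 CPM, and the chemokine gene Ccl5 was 2221 and 3856 CPM. Of 20 activation and checkpoint genes 18 were higher, 15 beyond it (0.34, percentile 100), with Havcr2 at 3.85 and 10.9 CPM and Pdcd1 at 18.7 and 35.3 CPM, and Ctla4 close at 108 and 107 CPM. Of 12 naive genes 11 were lower, each beyond its interval (-0.19, percentile 0), with Dapl1 at 224 and 149 CPM and Satb1 at 1438 and 1147 CPM. Without members that were also markers the medians were 0.49, 0.33 and -0.33. These genes lead the T-like clusters whose shares differed, so lists and shares are 1 observation. With clusters weighted to their WT make-up, the cytotoxicity, activation and naive medians were -0.07, -0.02 and -0.0091.

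Other T-like lists differed less. Endoplasmic reticulum stress genes were higher (0.18, percentile 99.99), with Xbp1 at 18.3 and 26.7 CPM. Immediate early genes had a median of 0.17 (20 of 30 higher, percentile 100), with Hspa8 at 802 and 1129 CPM. Ribosomal protein genes were lower in 46 of 54 cases (-0.15, percentile 0). The interferon list was lower (-0.10, percentile 0; Usp18 at 22.5 and 14.7 CPM), and stood at 0.0081 with free RNA subtracted. The p53 list (0.11, percentile 98.1) was at -0.08 with the WT make-up. Class I (0.05), respiratory (0.01), mitochondrial (-0.01) and cell cycle (0.08) medians stood at percentiles 83.6, 29.2, 39.2 and 88.6. Named genes higher in the het KO library were Gstp1 (8.04 and 61.2 CPM), Hist1h2ap (6.16 and 46.1 CPM), Gpx3, a secreted kidney enzyme (1.03 and 9.47 CPM), Traj33 (0.727 and 7.06 CPM) and Jchain (14.7 and 102 CPM, 77.1% in 5 cells). Lower were Rnaset2a (111 and 26.3 CPM), Rnaset2b (90.6 and 26.5 CPM, with a log2 ratio of 0.08 against the median of the other classes), Pou2f3 (6.16 and 0.964 CPM), Serpinb5 (82.3% of WT UMIs in 5 cells) and Hist1h4m. Hist1h4m had 66 WT UMIs and none in the het KO library, 21.5-fold lower against the floor of 3 counts. Transcripts of other cells were higher in het KO T-like cells, with Igkc at 114 and 891 CPM, Cd74 at 83.2 and 185 CPM and the proximal tubule gene Kap at 4.23 and 14.1 CPM.

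NK-like cells of the het KO library showed lower cytotoxicity transcripts. Of 20 such genes 15 were lower, 13 beyond their interval (median -0.11, percentile 0.30, and -0.11 without the 12 that were also markers), with the chemokine genes Ccl3 at 578 and 342 CPM and Ccl4 at 1700 and 1306 CPM, and Ifng, the interferon gamma gene, at 252 and 206 CPM. Klrg1 (98.3 and 109 CPM) and Cx3cr1 (42.6 and 49.5 CPM) were higher. Respiratory (-0.08, percentile 0) and ribosomal (-0.09, percentile 0.14) genes were lower, and endoplasmic reticulum stress genes higher (16 of 17; 0.17, percentile 100). Immediate early (0.02), interferon (-0.04), p53 (-0.01), cell cycle (-0.09) and class I (-0.0047) medians stood at percentiles 83.2, 25.4, 54.2, 17.9 and 47.4. The mitochondrially encoded median was 0.07. Named genes higher in the het KO library were Gpx3 (0.877 and 11.8 CPM), Gstp1 (6.84 and 51.3 CPM), Hist1h2ap (10.2 and 68.2 CPM), Il31ra (4.73 and 27.9 CPM) and the cytokine gene Il22. Il22 had no WT UMI and 79 het KO UMIs in 3 cells, 38.9-fold higher against the floor of 3 counts. Lower were Rnaset2a (152 and 32.9 CPM), Rnaset2b (154 and 36.5 CPM), Nutf2-ps1 (5.70 and 0.648 CPM), Kntc1 (51 and 3 UMIs, 66.7% of the WT ones in 5 cells) and Ccl1 (312 and 7 UMIs, 97.1% of the WT ones in 5 cells).

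B-like cells of the het KO library had fewer interferon-response transcripts, 35 of 40 genes, 19 of them beyond their interval (median -0.19, percentile 0), with Ifi27l2a at 505 and 350 CPM. This list stayed between -0.23 and -0.14 under the alternatives. Endoplasmic reticulum stress (0.18, percentile 100) and mitochondrially encoded genes (0.14, percentile 99.97) were higher, and immediate early genes slightly so (0.05, percentile 99.3; Hspa8 at 513 and 805 CPM). Class II genes (-0.07, percentile 4.44), with the regulator gene Ciita at 143 and 116 CPM, and ribosomal genes (-0.05, percentile 1.88) stood at the low side. Respiratory (-0.0039), class I (0.02), p53 (0.03) and cell cycle (-0.02) medians stood at percentiles 54.2, 78.9, 81.5 and 62.7. Named genes higher were Gstp1 (3.68 and 36.0 CPM), Hist1h2ap (10.6 and 78.7 CPM), Il31ra (4.19 and 26.5 CPM), Gpx3 (1.53 and 8.82 CPM) and C1qb (3.07 and 13.6 CPM). Lower were Kntc1 (6.03 and 0.735 CPM), Slfn4 (4.50 and 0.858 CPM), Phpt1 (18.9 and 5.64 CPM), Rnaset2a (61.9 and 18.7 CPM) and Ralyl (89.6% of WT UMIs in 5 cells). Dendritic-like cells, with 161 WT and 361 het KO cells, also had lower interferon genes (30 of 42, 17 beyond their interval; -0.19, percentile 0.52), with Cxcl10 at 15.9 and 5.90 CPM, and higher endoplasmic reticulum stress genes (15 of 17; 0.16, percentile 100). Antibody transcripts were higher in these dendritic-like cells as well, with Igha at 435 and 1947 CPM and Igkc at 1357 and 4978 CPM. The dendritic-like immediate early median was 0.06 (percentile 99.8), and -0.12 after thinning. Their class II (0.08), ribosomal (0.04) and cell cycle (0.11) medians stood at percentiles 96.8, 95.7 and 98.8.

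Tubule cells were few. Proximal tubule-like cells (19 WT and 77 het KO cells) had higher injury genes in the het KO library (11 of 14, 5 beyond their interval; median 0.79, percentile 99.99), with Cd44 at 6.79 and 128 CPM and S100a6 at 20.4 and 168 CPM, but 85.1% and 77.4% of the het KO UMIs of these genes lay in 5 cells. Among the 6 large immune classes both genes were highest in neutrophil-like cells (2490 and 6059 CPM, means of the libraries). The median doublet score of the proximal tubule-like cluster was 0.120. Whether leukocyte transcripts raised the injury list was not tested. Immediate early (0.64, percentile 99.99) and NRF2 target genes (0.33, percentile 99.7) had higher medians, each with 6 members higher beyond their interval. Mitochondrially encoded (-0.49, percentile 0; 10 of 13 lower beyond their interval) and ribosomal genes (-0.23, percentile 0.01; 31 of 54) were lower. Cholesterol synthesis (-0.42, percentile 1.68; 8 of 13 lower), interferon (-0.42, percentile 2.20; 9 of 11 lower) and respiratory medians (0.14, percentile 97.7; 46 of 65 higher) lay just outside the random lists, with 1, 1 and 11 members beyond their interval in that direction, and the interferon median was 0.0835 as a mean over cells. The glycolysis median (0.29, percentile 97.03) lay within them. Segment genes of S1 and S2 (0.05, percentile 71.3) and S3 (0.0009, percentile 57.9), androgen-responsive (-0.18, percentile 13.6), fatty acid oxidation (0.02, percentile 44.5), gluconeogenesis (0.17, percentile 89.5) and lysosome genes (0.10, percentile 74.2) lay within them too. Some of these cells carried transcripts of leukocytes. Lyz2 was 47.5 and 493 CPM, with 87.8% of the het KO UMIs in 5 cells, and the log2 ratios of Lyz2 and Malat1 were -1.48 and -5.29 with cells above a Scrublet score of 0.1 left out. By the named-gene rule Unc5c (0 and 127 UMIs, 6.60-fold against the floor of 3 counts), Slc51b, Lst1, Nhs, Gstp1 and Eno1 were higher, and Ccnd1 (400 and 96.4 CPM), Dnase1 (455 and 174 CPM), Kcnq5, Malt1, Lncpint and the lymphocyte genes Trbc2, Satb1, Bach2, Aff3 and Ebf1 lower. All 127 Unc5c UMIs lay in 5 cells, as did 95.7% of Nhs and 85.9% of Lst1 UMIs of the het KO library. Of the lower genes other than Dnase1, 96.7% or more of the WT UMIs lay in 5 cells, and the 21 Trbc2 UMIs lay in 1 cell. After thinning, the log2 ratios of Unc5c, Slc51b, S100a6, Nhs and Gstp1 were below 0. Thick ascending limb-like cells (127 and 84 cells) had higher class I genes (13 of 17, 5 beyond their interval; 0.35, percentile 99.9), with the immunoproteasome gene Psmb9 at 7.12 and 18.0 CPM. Some leukocyte transcripts were higher in the same cells, with C1qa at 1.94 and 37.9 CPM and Cd74 at 238 and 325 CPM, while S100a8 was lower at 423 and 29.8 CPM, and the median doublet score of this cluster was 0.108. The same cells had lower transport genes (11 of 15, 5 beyond it; -0.15, percentile 1.27), with the chloride channel subunit gene Bsnd at 102 and 83.0 CPM. Their immediate early (0.15), respiratory (-0.08), ribosomal (0.07), interferon (0.06) and endoplasmic reticulum stress (-0.13) medians stood at percentiles 99.7, 0.46, 99.9, 76.2 and 9.82, and the respiratory one was 0.0042 after thinning.

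Some genes differed alike in all 6 large immune classes. Of 7734 genes read in each of them, the 20 with the highest and the 20 with the lowest shared ratio were listed, a ranking made after the data were seen. Higher in the het KO library in every class were Rpl35 (30042 and 93203 UMIs; median log2 ratio 1.79), Eno1 (1.58), Bcl2a1d (1.74), Hist1h2ap (505 and 3093 UMIs) and the predicted gene Gm10076 (2.73). Lower were Rnaset2a (-2.07), Rps27rt (-2.14), Rpl9-ps6 (-2.15), Rpl10-ps3 (-1.25) and Ftl1-ps1 (-1.06). Against the median of the other classes, Rnaset2a in B-like cells had a log2 ratio of 0.35, Il31ra in neutrophil-like cells one of -0.0867 and Gstp1 in monocyte-like cells one of -0.0032. Many of these share sequence with near-identical copies, such as Rps27rt with Rps27, Rpl9-ps6 with Rpl9 and Rpl10-ps3 with Rpl10 (0.89), so their levels are uncertain. H2-Q4 and H2-Q6 led the class I list in immune classes, with H2-Q4 at 49.1 and 103 CPM in macrophage-like cells, and are of this kind. Hemoglobin transcripts went both ways, with medians of 1.35 in NK-like and -2.71 in neutrophil-like cells. Without stress, mitochondrial, ribosomal and hemoglobin genes in the clustering the NK-like value was -0.86, and with cells above a Scrublet score of 0.1 left out the neutrophil-like value was 0.45.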

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

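The tests on the origin of Axl UMIs in lymphocytes were chosen after that result was seen. The differences between cell classes below were not tested, because each genotype had 1 library.

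Axl went in opposite directions in different classes, with a log2 ratio of 1.67 in NK-like and -1.15 in monocyte-like cells, a difference of 2.82. Free RNA from macrophages could add Axl to lymphocytes, and would then keep Axl and the C1q genes in the ratio seen in macrophages. Per 1000 C1q UMIs there were 19.5 Axl UMIs in het KO macrophage-like cells, 129 in T-like and 138 in NK-like cells, so the ratio in T-like cells was 6.63 times (5.28 to 8.24) that of macrophages, and in the WT library 11.2 times (8.13 to 15.2) in T-like and 5.35 times (3.11 to 8.74) in NK-like cells, which argues against macrophage RNA as the main source. Free RNA with the profile of all cells, at the shares set by proximal tubule genes (19.9% and 8.57%), would give 2.44 and 1.05 CPM of Axl there, against 2.44 (1.85 to 3.16) and 1.67 CPM measured, and in the het KO library 1.83 and 1.24 CPM, below the 4.08 (3.29 to 4.99) and 5.31 CPM (3.81 to 7.21) measured. The WT share would also give T-like cells 56.7 CPM of C1q, where 7.06 CPM was measured, so these shares are in doubt, and expression by the lymphocytes and free RNA of other cells cannot be told apart. In B-like cells the multiple was 3.08 (1.73 to 5.09) in the het KO and 1.88 (0.596 to 4.57) in the WT library, and from 5 WT UMIs the explanations cannot be told apart there.

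Mertk was higher in het KO macrophage-like cells (log2 ratio 0.54) and lower in monocyte-like cells (-0.996), a difference of 1.53, although one monocyte-like cluster had 37 and 9 Mertk UMIs and another 0 and 5. Ribosomal protein genes were higher in het KO neutrophil-like cells (0.37) and lower in T-like cells (-0.15), a difference of 0.52. Cytotoxicity genes were higher in het KO T-like cells (0.51) and lower in NK-like cells (-0.11), a difference of 0.62, but the T-like value was -0.072 when weighted to the WT cluster make-up.

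Barcodes above 50% mitochondrial UMIs, which the main setting left out, made up 1.80% (1.55 to 2.08; 184 barcodes) of the het KO library and 0.866% (0.697 to 1.06; 90 barcodes) of the WT library. The alternative without a mitochondrial limit and the choice of barcodes by C1q UMIs did not leave them out. They were rich in tubule transcripts. In this paragraph CPM is without mitochondrial genes, both for these barcodes and for the cells used. Counts were divided by nuclear UMIs alone and not by all UMIs. With mitochondrial UMIs in the total the values would be lower, most of all in these barcodes. Umod, the main secreted protein gene of the thick ascending limb, was 8357 CPM in the WT and 6872 CPM in the het KO barcodes, against 371 and 236 CPM in the cells used. The leukocyte gene Ptprc was 422 and 420 CPM, against 1713 and 1569 CPM. The shares of tubule classes given above leave these barcodes out.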

How the results depend on the processing

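Removal of cells with a Scrublet score above 0.1, weighting to the WT cluster make-up and subtraction of the median of the other classes were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library, and for the same reason no replicate could be left out. Of the list medians under alternatives, 1455 stayed within a range as wide as the central 95% of random lists, 177 moved further, and 22 that had lain outside the random lists changed sign, as did some medians inside them. For genes, judged by their counting interval, 1207 stayed, 165 moved and 23 with an interval excluding no change reversed, and for shares of cells 129 stayed and 7 moved. Axl in macrophage-like cells stayed between -1.08 and -0.82 over 14 alternatives, Axl in NK-like cells between 1.52 and 2.70, and the macrophage-like share between 1.90 and 2.01. CPM without mitochondrial genes reversed no list outside the random lists and no gene whose interval excluded no change. Values below are log2 ratios of het KO over WT, and for each of them the cause was not tested. Counts limit the proximal tubule-like class, with 19 WT and 77 het KO cells.

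With mitochondrial UMIs up to 25%, the proximal tubule value of Malat1 reversed to -0.85. In neutrophil-like cells immediate early genes were 0.10, interferon -0.39, mitochondrial 0.25, ribosomal 0.19 and activation -0.0134. In macrophage-like cells monocyte-derived genes were 1.13 and cell cycle -1.12. With no mitochondrial limit, Ebf1 in proximal tubule-like cells reversed to 0.54 and dendritic immediate early genes to -0.0266. Neutrophil mitochondrial, ribosomal and activation genes were 0.20, 0.18 and -0.0151, and macrophage cell cycle -0.21.

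With at least 500 genes per cell, the erythroid share was 0.65, monocyte mitochondrial genes 0.0271, neutrophil ribosomal genes 0.28, and macrophage monocyte-derived and cell cycle genes 0.18 and -0.97. Hemoglobin reversed to 0.33 in B-like and 3.04 in dendritic-like cells. With called doublets kept, Jchain in macrophage-like cells reversed to -0.13 and hemoglobin in B-like cells to 1.204. NK interferon genes were -0.12, neutrophil mitochondrial and ribosomal genes 0.25 and 0.22, macrophage ribosomal and cell cycle genes -0.0126 and -1.11, B class II genes -0.14 and T cytotoxicity 0.62.

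At resolution 0.5, T-like clusters 10 and 14 merged, with a share of 0.68 for both. Dendritic immediate early genes reversed to -0.0152, neutrophil ribosomal genes were 0.25 and macrophage monocyte-derived genes 1.10. At resolution 2, the share of T-like cluster 3 was -0.18. With stress, mitochondrial, ribosomal and hemoglobin genes left out of clustering, hemoglobin reversed to -0.86 in NK-like and 0.31 in B-like cells, neutrophil ribosomal genes were 0.28 and macrophage cell cycle genes -1.60.

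Without cells above a Scrublet score of 0.1, shares were -1.93 for thick ascending limb, 1.55 for dendritic and 3.20 for T-like cluster 14. Proximal tubule Lyz2 reversed to -1.48 and Malat1 to -5.29. Macrophage interferon, respiratory, endoplasmic reticulum stress, monocyte-derived and cell cycle genes were -0.0425, -0.20, 0.11, 0.70 and -0.996. Monocyte mitochondrial and class II genes were 0.0156 and -0.41. Hemoglobin reversed to 0.45 in neutrophil-like, 1.15 in B-like and 3.81 in dendritic-like cells. Neutrophil ribosomal genes were 0.21 and T cytotoxicity 0.61.

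With median-of-ratios scaling, monocyte immediate early, interferon, respiratory and ribosomal genes were 0.18, 0.0205, -0.0759 and 0.0442, and neutrophil respiratory and ribosomal genes 0.0095 and 0.26.

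After thinning to 1000 UMIs, Axl was -1.08 in macrophage-like and -0.46 in monocyte-like cells, Gas6 in macrophage-like cells 1.90 and Pros1 in monocyte-like cells 0.23. In proximal tubule-like cells Unc5c (-1.42), Gstp1 (-0.16), Slc51b (-1.42), S100a6 (-0.94), Nhs (-0.75) and Aff3 (0.84) reversed, as did Hist1h2ap in macrophage-like cells (-0.0031). Immediate early genes were 0.18 in monocyte-like cells and reversed to -0.12 in dendritic-like cells. Interferon genes were -0.23 in macrophage-like and -0.12 in NK-like cells. Thick ascending limb respiratory genes reversed to 0.0042. Class I genes were -0.10 in monocyte-like and 0.18 in neutrophil-like cells. Endoplasmic reticulum stress genes were 0.0043 in monocyte-like, 0.21 in neutrophil-like and 0.0726 in B-like cells. The p53 list reversed to -0.13 in macrophage-like cells and was 0.19 in monocyte-like and 0.16 in B-like cells. Macrophage efferocytosis, resident, monocyte-derived and cell cycle genes were -0.12, -0.10, 0.15 and -0.10, and T cell cycle genes 0.31.

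The shares of free RNA are in doubt, as given above, and this holds for all values of this paragraph. With free RNA subtracted, Axl was -1.02 in macrophage-like, 3.96 in T-like and 2.70 in NK-like cells. T immediate early, respiratory, p53, cytotoxicity, naive and cell cycle genes were 0.27, 0.0824, 0.25, 0.89, -0.30 and 0.25, and T interferon genes reversed to 0.0081. NK interferon genes were 0.0465. Macrophage respiratory and ribosomal genes reversed to 0.0232 and 0.0529, and class II, lysosome, monocyte-derived and glycolysis genes were -0.20, -0.24, 1.27 and 0.18. Neutrophil respiratory and ribosomal genes were 0.23 and 2.15, and monocyte ribosomal and cell cycle genes 0.027 and 0.0657.

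With the mean over cells, dendritic immediate early genes reversed to -0.0265, proximal tubule interferon genes to 0.0835 and thick ascending limb respiratory genes to 0.0237. Monocyte endoplasmic reticulum stress and inflammatory genes were 0.0739 and 0.21, and macrophage monocyte-derived genes 0.21.

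Weighted to the WT cluster make-up, T cytotoxicity, activation and p53 genes reversed to -0.072, -0.0217 and -0.0771. T immediate early, interferon, respiratory, class I, ribosomal, naive and cell cycle genes were 0.10, -0.19, -0.0595, -0.0474, -0.0589, -0.0091 and -0.13. Monocyte interferon genes were -0.10 and neutrophil ribosomal genes 0.28.

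Minus the median of the other classes, Hist1h2ap reversed to -0.92 in macrophage-like, -0.25 in monocyte-like and -0.14 in NK-like cells, and Gstp1 to -0.71, -0.0032 and -0.0134 in the same classes. Bcl2a1d in macrophage-like cells reversed to -0.32, Rnaset2a to 0.0148 in monocyte-like and 0.35 in B-like cells, Il31ra in neutrophil-like cells to -0.0867 and Rnaset2b in T-like cells to 0.0771. With list members of at least 100 UMIs, macrophage monocyte-derived genes were 0.087. With at least 200 UMIs per named gene, 13 of the 20 named macrophage genes and 5 of the 20 proximal tubule genes were left, and 5 or 6 of 10 in the other classes.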

Other observations

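The genes of the first 2 paragraphs, and the residual blood and clustering tests on the macrophage-like share, were chosen after the results were seen.

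Some genes outside the lists, taken here for their values within 1 class, differed between the libraries. In neutrophil-like cells the surface protein gene Ly6g was 186 CPM in the WT and 62.3 CPM in the het KO library, and Tspo, of the outer mitochondrial membrane, was 674 and 260 CPM. In T-like cells Traj18, a junction segment used by invariant natural killer T cells, was 30.7 and 8.68 CPM, and Cd163l1, a gene of γδ T cells, was lower as well, with 48.4 CPM in the WT library. In monocyte-like cells Spon1 was 27.0 and 7.80 CPM and the granule protease gene Prtn3 32.3 and 12.8 CPM, while Gas7 was higher at 104 and 186 CPM. In macrophage-like cells Sash1 was 30.9 and 56.2 CPM, and Clec9a, a receptor gene of conventional dendritic cells, was 51.8 and 22.3 CPM.

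In thick ascending limb-like cells the interferon-induced genes Gbp2 and Igtp were 1.30 and 45.1 CPM and 1.30 and 27.1 CPM, from few cells, while 10 members of the interferon list were higher there and 10 lower. Axl in mast and basophil-like cells was 17.9 and 44.0 CPM, a ratio of 2.46 (1.17 to 5.51; 11 and 26 UMIs). Antibody genes went both ways. Igha was 34.7 and 334 CPM in T-like and 227 and 108 CPM in B-like cells, and Iglc1 was lower in all 6 large classes (9572 and 4871 UMIs; median log2 ratio -1.50).

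The macrophage-like share was higher in the het KO library. Clustering, doublet calls or the gene and mitochondrial limits could have made this. Without these steps, among all barcodes of at least 1000 UMIs thinned to that depth (197 WT and 231 het KO ones left out), 2.93% of WT and 10.3% of het KO barcodes held at least 2 C1q UMIs, a ratio of 3.51, which argues against it. Less blood left in the het KO kidneys may lower circulating cells, and NK-like, monocyte-like, neutrophil-like and B-like shares were lower. The naive-like T clusters were lower too (0.760 and 0.762). The T-like ratio of 1.02 pools these with clusters that were higher, so it does not bear on this. Erythroid-like cells had a ratio of 2.25, which goes against less blood, although hemoglobin transcripts went both ways between classes. Less blood as a part of the cause is left open. An effect of the genotype and a difference in digestion or capture between the libraries cannot be told apart with 1 library per genotype.

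The genes shifted alike in all 6 large classes may have another origin than the genotype. Reads shared between near-identical copies could split unlike in the 2 libraries, and 77.5% (61.5 to 89.2) of the 40 genes had such a copy, against 25.6% of 7730 genes, 3.03 times as many, just above the 3 times set in advance, which goes with that explanation for part of the genes. Rnaset2a and Rnaset2b, the one copy found for Rnaset2a, were lower together (-2.18 and -2.24 in macrophage-like cells). A split of reads between this pair alone would not give that. The pair does not speak on other ways in which shared reads could be counted, which were not tested. Variants carried along with the Axl locus would place these genes near Axl on chromosome 7, and 0 of the 40 (0%, up to 8.81%) lay within 20 Mb, against 2.41% of all genes read, so the shift as a whole does not come from that region. Why shared reads would split differently was not measured, and a difference in preparation, sequencing or counting cannot be told apart from the genotype with 1 library of each. Among the 40 genes, Kap and S100a9 had no such copy. In T-like cells Kap was 4.23 and 14.1 CPM and S100a9 117 and 66.4 CPM in the WT and het KO library. Whether free RNA of tubule cells or neutrophils made the shift of such genes was not tested.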
